A study of Homo sapiens with 8 samples.

How the data were processed

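H3K27ac ChIP-seq was done in A549 cells and in MSR-A549 cells, a derivative selected and kept in momelotinib and selumetinib. Per the labels' protocols, both lines grew in DMEM with 10% fetal bovine serum. Histone-DNA complexes were isolated from sonicated nuclei with an H3K27ac antibody, libraries were made from 2 ng of precipitated DNA, and 75-bp single-end reads were sequenced on a NextSeq instrument. The labels list 4 H3K27ac samples and 4 input DNA samples, 2 of each per line. They do not say whether the samples of a line came from separate cultures.

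Per the submitters' processing notes, the authors used the aligner Bowtie2 (version not given in the sources used here), the peak caller MACS 1.4.2 and the genome build hg19. Each deposited list names its samples as merged, so it was taken as called on the pooled H3K27ac samples of 1 line. The list named for resistant cells was taken as MSR-A549. Whether input DNA served as the control, how duplicate reads were treated and how deep each library was are not given in the sources used here. Each list gives the position of every peak and, as the authors' score per peak, a value whose minimum of 50 equals -10 times log10 of a p of 1e-05. Many peaks are tied at a score of 3100, and the highest score, 3233.06, is the same in both lists. The order of peaks at or above 3100 need not follow their strength. The score grows with read depth, so it was used to describe, rank and filter peaks within a list. Where the same minimum score was applied to both lists and the remaining peaks counted, those counts depend on the unknown depth too. A deeper library also gives more and longer peaks, and the depth is unknown, so a difference in peak number or covered length between the lists can come from depth as well as from acetylation. Input reads and signal tracks were not analysed here.

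From these lists, a peak was called shared when at least 1 base overlapped a peak of the other list and found in a single line otherwise (bedtools 2.31.1). Shares are given with exact (Clopper-Pearson) 95% binomial intervals, and ratios of peak numbers with exact conditional binomial intervals. They cover counting error only. As a background, the MSR-A549 list was shifted along each chromosome by 1 to 10 Mb. Covered length was the number of bases under peaks, in fixed windows of 50 kb, in segments of 5 Mb and per chromosome. Log2 cover ratios were taken over segments with at least 50 kb of cover in both lists together and some cover in each. Neighbouring windows that each gained or lost at least 10 kb were joined. Peaks that overlapped exactly 1 peak of the other list, and were its sole partner, were compared in length. Strong or long peaks found in a single line and within 100 kb of each other were counted as 1 locus. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap and window code was tested on simulated lists made from the A549 peaks, in which all 500 dropped peaks, 720 added peaks and 20 gained domains were recovered.

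The overlap counts and shares and the rule for named regions were fixed before the data were examined. The rule named genes from fixed lists and genes around which cover changed most, and where no annotation of the files' build was at hand it named fixed 50-kb windows by position. That second form was used: the 10 windows with the largest gain and the 10 with the largest loss of covered length, and the 3 peaks with the highest score among those found in each line alone. Ties in score at 3100 were broken by length, a choice the rule did not state. The annotation used here was on GRCh38, and positions were not converted between builds. Results planned for promoters, distal peaks, gene lists and named genes were therefore not computed. With 1 pooled list per line, no replicate comparison, test or p-value was possible. Alternatives fixed in advance were a minimum score of 100, equal numbers of peaks, equal covered length, merging of peaks within 1000 bp, a minimum of 50% of the peak covered, and counting peaks within 1000 bp as shared. Lists without chromosome 8 or without unplaced sequences (59 peaks in A549, 69 in MSR-A549) were added after the data were seen.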

Results

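H3K27 acetylation (H3K27ac), a histone mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in 2 human lung cancer lines. A549 is an established lung adenocarcinoma line, and its samples were labelled with the solvent DMSO. MSR-A549 was derived from it over 2 months of alternating culture in drug-free medium and in medium with 5 µM momelotinib, a JAK inhibitor that also blocks TBK1, and 1 µM selumetinib, a MEK inhibitor. MSR-A549 was then kept in both drugs, so the lines differed in selection history and in drug exposure together. Each line had 2 H3K27ac samples and 2 input DNA samples, 8 samples in all. The peaks analysed here came as 1 pooled list per line. There was therefore no spread between replicates, no test of a difference and no p-value. Read depth was unknown. The A549 list held 62005 peaks over 144.0 Mb, with a median length of 1475 bp (interquartile range 907 to 2636 bp). The MSR-A549 list held 66309 peaks over 147.8 Mb, with a median length of 1422 bp (850 to 2595 bp). All coordinates are on hg19 and count from 1. No hg19 gene annotation was used here, so regions are given by position only.

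The comparison asked where H3K27ac differs between the parental and the drug-resistant line. MSR-A549 had long acetylated domains that were nearly absent from A549 on chromosomes 15, 4 and 6. Between 67350001 and 67500000 on chromosome 15, peaks covered 2.72 kb in A549 and 134.7 kb in MSR-A549. Between 41300001 and 41650000 on chromosome 4, they covered 10.8 kb and 212.8 kb. In the other direction, A549 had wider domains along chromosome 8, where total cover was 6.91 Mb in A549 and 4.81 Mb in MSR-A549. A loss of DNA copies in MSR-A549 could also give this lower cover, and input reads were not analysed here. Most of the mark was common to both lines, since 74.8% of A549 peaks overlapped an MSR-A549 peak.

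Cover was compared in fixed windows of 50 kb, and the 10 windows with the largest gain in MSR-A549 fell on chromosomes 15, 4, 6, 12 and 1. The top gain was at chromosome 15, 67400001 to 67450000, with no A549 peak and 49.0 kb under MSR-A549 peaks. The windows on either side of it, starting at 67350001 and 67450001, went from 1.20 to 46.4 kb and from 1.51 to 39.4 kb. A separate window on chromosome 15, 59550001 to 59600000, had no A549 peak and 47.5 kb of MSR-A549 peaks. On chromosome 4, cover in the adjoining windows from 41400001 and 41450001 was 2.96 and 1.08 kb in A549 and 45.0 and 37.8 kb in MSR-A549. On chromosome 6, the window from 136700001 had no A549 peak and 38.4 kb in MSR-A549, and that from 136800001 had 0.685 kb and 41.6 kb. At chromosome 12, 20550001 to 20600000, cover was 3.32 kb in A549 and 42.5 kb in MSR-A549. At chromosome 1, 201150001 to 201200000, it was 4.44 and 41.1 kb. Joining neighbouring windows that each gained at least 10 kb gave wider domains. The domain on chromosome 4 spanned 350 kb with 19.6-fold more cover in MSR-A549, that on chromosome 15 spanned 150 kb with 49.6-fold more, and that at chromosome 6, 136700001 to 136900000, spanned 200 kb with 69.3-fold more (1.84 against 127.6 kb). The domain at chromosome 12, 20500001 to 20800000, was already acetylated in A549 and had 2.06-fold more cover in MSR-A549 (108.2 against 222.5 kb). These folds are ratios of covered length, not of signal.

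**Figure D1:**
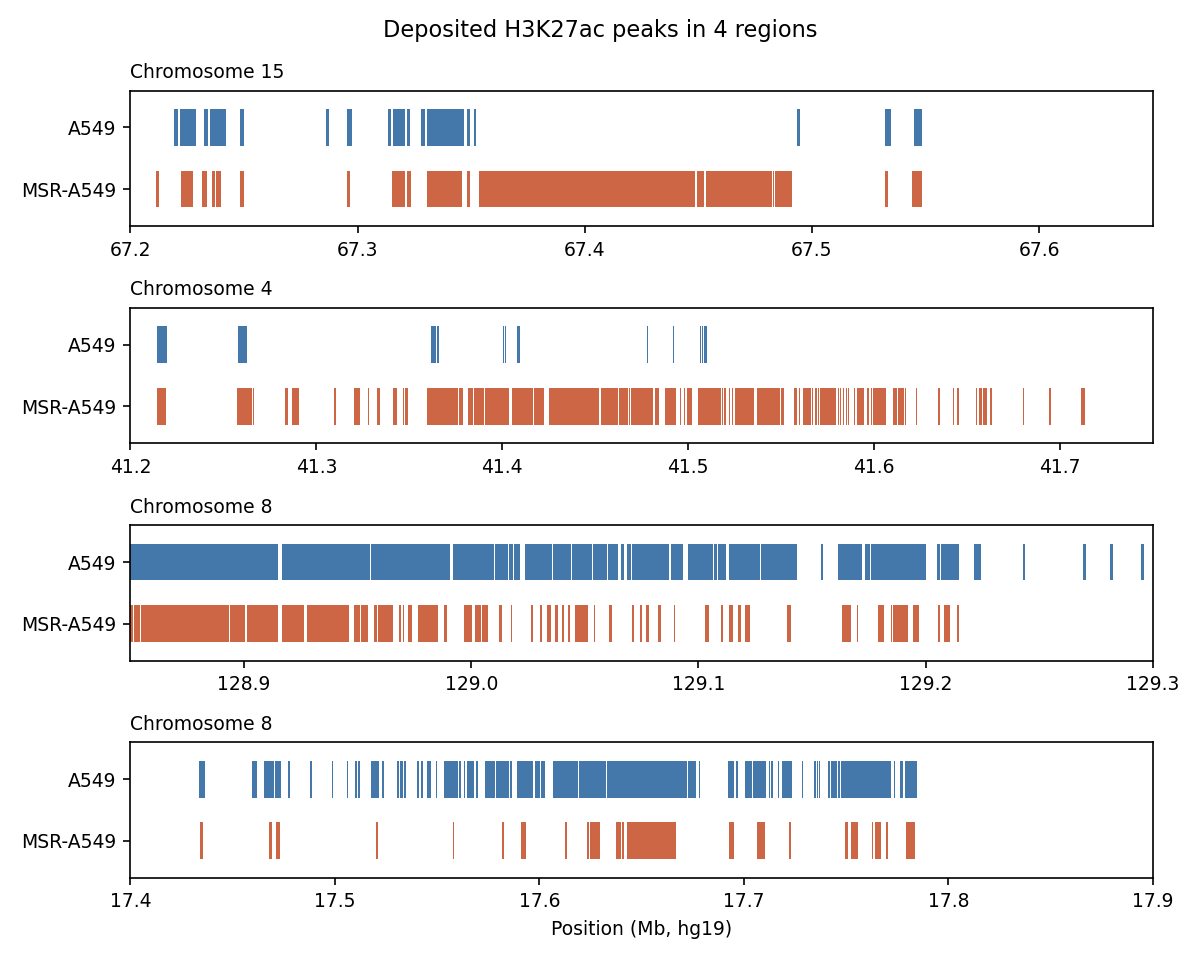
Deposited H3K27ac peaks of A549 (blue) and MSR-A549 (orange) in 4 regions, drawn to scale against position on hg19 in Mb; each filled block is 1 peak. In the chromosome 15 and chromosome 4 regions MSR-A549 has long peaks where A549 has few, and in both chromosome 8 regions A549 has the wider cover.

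The 10 windows with the largest loss in MSR-A549 lay on chromosomes 8, 11, 16, 1 and 20, and 4 of them were on chromosome 8. At chromosome 16, 81550001 to 81600000, cover went from 49.8 kb in A549 to 8.88 kb in MSR-A549. At chromosome 1, 161400001 to 161450000, A549 peaks covered 33.0 kb and MSR-A549 had no peak. On chromosome 8, the windows from 129050001 and 129100001 went from 42.9 to 8.73 kb and from 41.2 to 9.74 kb. Those from 17550001 and 17600001 on the same chromosome went from 34.6 to 4.12 kb and from 45.1 to 16.6 kb. On chromosome 11, cover went from 38.6 to 8.81 kb in the window from 57200001 and from 32.7 to 3.56 kb in that from 16900001. The remaining windows were at chromosome 20, 46150001 to 46200000 (38.0 to 8.08 kb), and chromosome 16, 15600001 to 15650000 (34.9 to 5.91 kb). MSR-A549 still had peaks in 9 of these 10 windows. The joined domain at chromosome 8, 128950001 to 129200000, had 214.5 kb of cover in A549 and 82.8 kb in MSR-A549, 2.59-fold less. That at chromosome 8, 17500001 to 17800000, had 183.2 and 59.4 kb, 3.09-fold less. Of the 28130 windows with a peak in either line, 256 gained at least 10 kb in MSR-A549 and 400 lost at least 10 kb.

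Chromosome 8 stood apart from the other autosomes. It carried 3031 peaks in A549 and 2472 in MSR-A549, a ratio of 0.816 (exact 95% interval 0.773 to 0.860), while the ratio of the other 21 autosomes ran from 0.959 to 1.25. Its covered length was 0.695 of that in A549, against 0.879 to 1.20 for the others. Of the A549 peaks on chromosome 8, 40.3% had no MSR-A549 peak, against 18.5% to 31.7% elsewhere, and the chromosome held 1223 peaks found only in A549 and 439 found only in MSR-A549. Among its 1509 peaks with a single partner in the other list, 68.9% were shorter in MSR-A549, against 37.6% to 62.2% on other autosomes. The median log2 ratio of their lengths was -0.18, and over the 36315 such pairs of all chromosomes it was 0.02. The lower cover ran along the chromosome, in 27 of its 30 segments of 5 Mb (90.0%), against 184 of 514 segments on other autosomes (35.8%). Of the single autosomes, chromosome 16 came nearest, with 11 of 15 segments (73.3%). The lowest log2 cover ratio of chromosome 8, -1.26, was at 45000001 to 50000000. Its 3 exceptions started at 70000001, 75000001 and 135000001, with log2 cover ratios of 0.04, 0.15 and 0.92. Chromosome 8 held 59 of the 400 windows that lost at least 10 kb (14.8%) but 4.53% of all windows with a peak. The intervals cover counting error only and take peaks as independent, which neighbouring peaks are not.

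**Figure D2:**
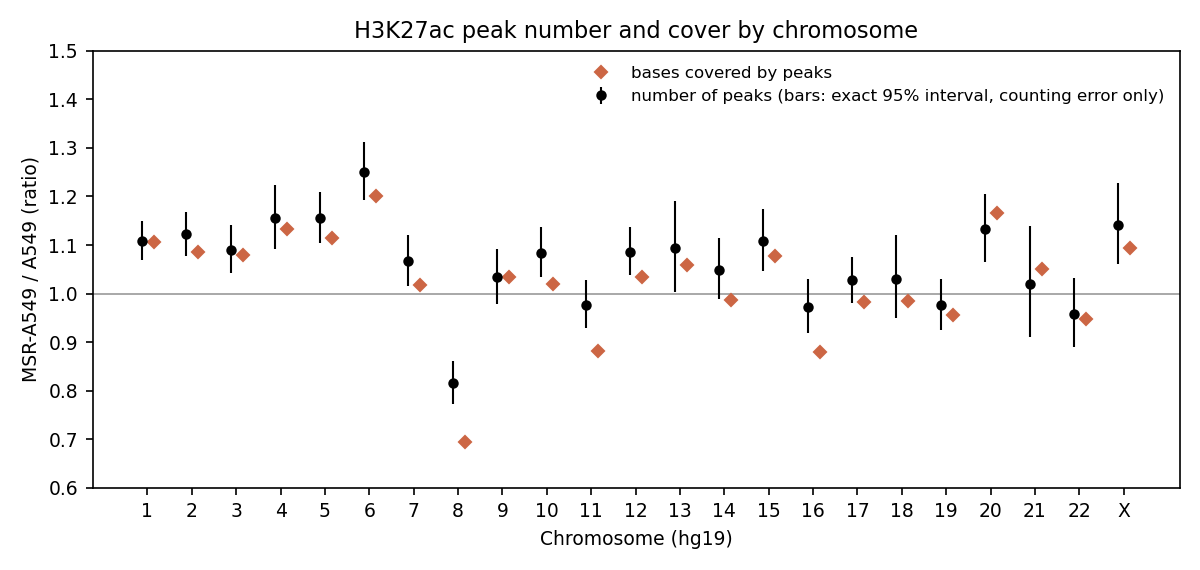
Ratio of MSR-A549 to A549 for each chromosome, as number of peaks (circles, bars are exact 95% intervals covering counting error only) and as bases covered by peaks (diamonds). Chromosome 8 has the lowest ratios, 0.816 for peaks and 0.695 for bases, and chromosome 6 the highest, 1.25 and 1.20.

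Chromosome 6 had the highest ratios of the autosomes, with 3059 peaks in A549 and 3827 in MSR-A549, a ratio of 1.25 (1.19 to 1.31), and 1.20 times the cover. It held 567 peaks found only in A549 and 1337 found only in MSR-A549. Its cover was higher in MSR-A549 in 28 of 34 segments, against 330 of 514 over all autosomes other than chromosome 8. Chromosome 20 followed with 1.17 times the cover and 1938 and 2196 peaks. It held 23 of the 256 windows that gained at least 10 kb (8.98%) and 13 of the 400 that lost as much (3.25%). Its share of all windows with a peak was 2.61%. As for chromosome 8, a difference in DNA copies could also give the higher cover of chromosomes 6 and 20, and input reads were not analysed here. Chromosomes 16 and 11 had the lowest cover ratios after chromosome 8, 0.879 and 0.882. Their peak number ratios were 0.973 (0.919 to 1.03) and 0.977 (0.928 to 1.03). These intervals included 1, but the MSR-A549 list as a whole held 6.94% more peaks, and both lay below that level. Across the 22 autosomes, 17 had more peaks in MSR-A549 and 5 had fewer, with the interval above 1 for 12 and below 1 for chromosome 8 alone. These counts partly restate the longer MSR-A549 list. Set against its 6.94% more peaks, the interval lay above that level for chromosomes 2, 4, 5 and 6. It lay below for chromosomes 8, 11, 16, 19 and 22. The comparisons by chromosome and by 5-Mb segment, the joined domains and the counts of windows by size were chosen after the data were seen.

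**Figure D3:**
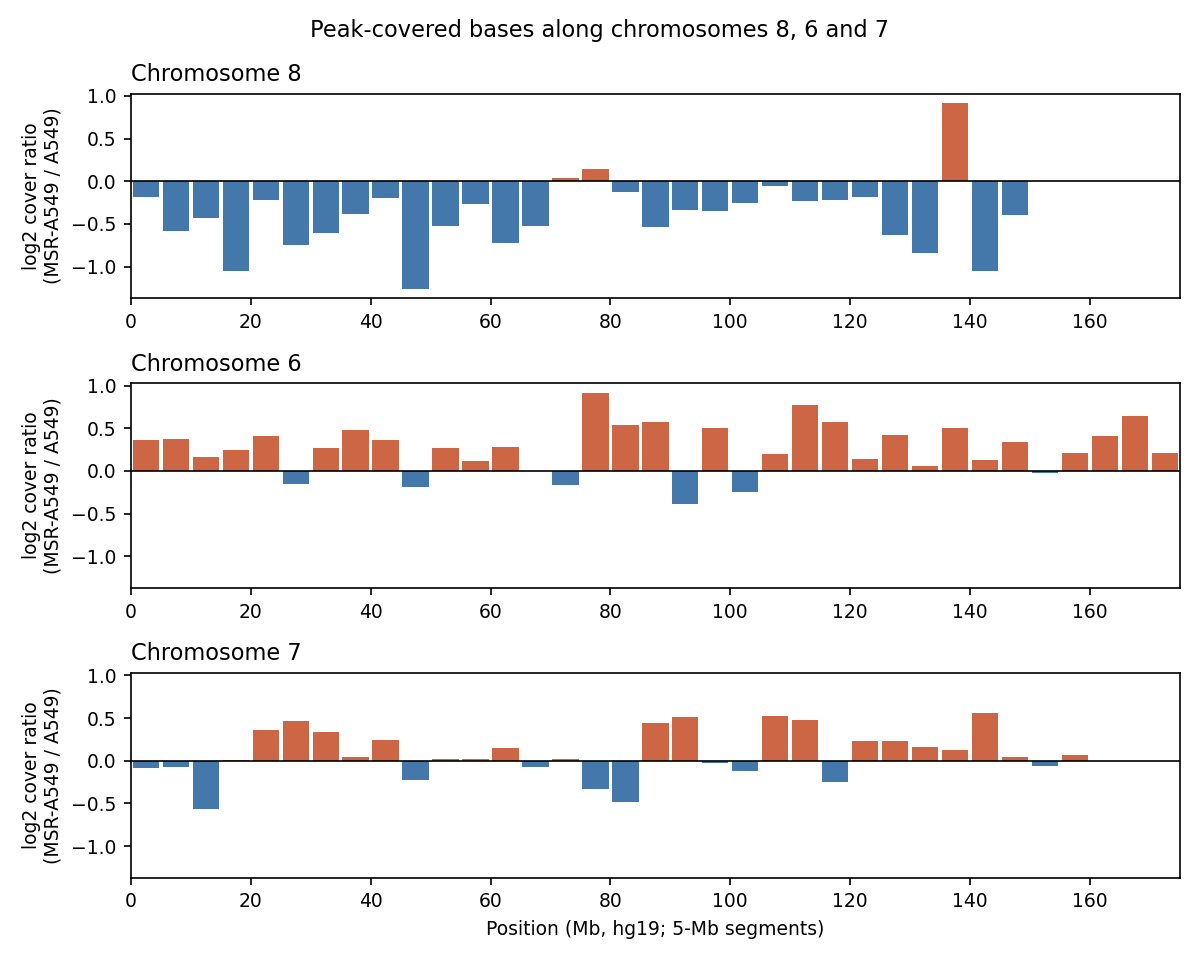
Log2 ratio of the bases covered by H3K27ac peaks, MSR-A549 over A549, in 5-Mb segments along chromosomes 8, 6 and 7 (position in Mb, hg19); blue bars are lower and orange bars higher in MSR-A549. Cover was lower in 27 of 30 segments of chromosome 8 and higher in 28 of 34 segments of chromosome 6 and 21 of 32 of chromosome 7. Over all autosomes other than chromosome 8 it was higher in 330 of 514.

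Peaks present in a single line were mostly short and weak. Sharing at least 1 base counted as overlap. By this rule 46391 A549 peaks (74.8%, exact 95% interval 74.5% to 75.2%) and 47393 MSR-A549 peaks (71.5%, 71.1% to 71.8%) were shared. This left 15614 peaks found only in A549 and 18916 found only in MSR-A549. When the MSR-A549 list was shifted along the chromosomes by 1 to 10 Mb as a background, 9.81% to 12.9% of A549 peaks were overlapped (median 10.3% of 10 shifts). Peaks found in 1 list had median lengths of 882 bp in A549 and 859 bp in MSR-A549, against 1861 and 1838 bp for shared peaks. Their median authors' scores were 94.7 and 101, against 748 and 745 for shared peaks. The larger number of MSR-A549-only peaks depended on list size. With the longer list reduced to the same number of peaks, 16616 were found only in A549 and 16087 only in MSR-A549, and with equal covered length the counts were 17023 and 15087.

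Strong peaks found in a single line were few. Strength was read from the score, the authors' own value for each peak, which ranks peaks within a list below 3100. At 3100 and above, a higher score need not mark a stronger peak. It depends on read depth, which is unknown, so a given score need not mark the same strength in both lists, which limits the counts that follow. At a score of at least 1000, 218 of 21360 A549 peaks (1.02%, 0.890% to 1.16%) and 601 of 22141 MSR-A549 peaks (2.71%, 2.5% to 2.94%) had no counterpart. At 3100, where most of the strongest peaks were tied, the counts were 22 (0.157%, 0.0986% to 0.238%) and 106 (0.773%, 0.634% to 0.935%). The 106 MSR-A549 peaks lay in 89 separate loci, 2 of the peaks on chromosome 8, and the 22 A549 peaks lay in 21 loci, none on chromosome 8. When a peak counted as shared only if 50% of it was covered, the counts were 1137 and 1543 at 1000 and 367 and 505 at 3100. After peaks under a score of 100 were dropped from both lists, the counts were 365 and 808 at 1000 and 39 and 142 at 3100. These score classes were chosen after the data were seen.

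**Figure D4:**
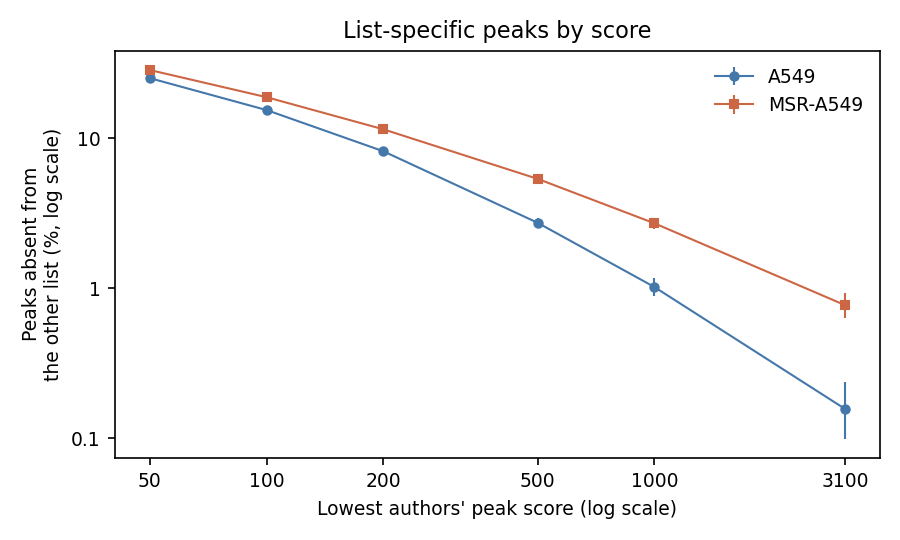
Percent of peaks without an overlapping peak in the other list (log axis) against the lowest authors' score included (log axis), for A549 (circles) and MSR-A549 (squares); bars are exact 95% intervals covering counting error only. The share falls with score in both lists and is 0.773% in MSR-A549 and 0.157% in A549 for scores of 3100 or more; equal scores need not mean equal strength, since read depth is unknown.

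The highest-scoring peaks found only in MSR-A549 were at chromosome 7, 137650257 to 137657385 (7129 bp, score 3223), chromosome 3, 33831254 to 33834464 (3211 bp, score 3179), and chromosome 5, 123089541 to 123093826 (4286 bp, score 3175). The nearest A549 peaks were 5.52, 1.98 and 45.5 kb away. Those found only in A549 were at chromosome 2, 238129895 to 238133909 (4015 bp, score 3112), chromosome 7, 37452298 to 37457009 (4712 bp, score 3109), and chromosome 11, 16904405 to 16917750 (13346 bp, score 3100). The nearest MSR-A549 peaks were 18.7, 30.2 and 26.2 kb away. These peaks need not be the strongest, since scores above 3100 need not mark stronger peaks than the many tied at 3100. The chromosome 11 peak lies in the window that lost cover from 16900001. Of peaks of at least 10 kb, 19 of 1178 in MSR-A549 and 5 of 1301 in A549 had no counterpart. They lay in 10 and 4 loci, and 11 and 4 of them overlapped the windows named above. The longest of these in MSR-A549 was a 43.1-kb peak at chromosome 15, 67405423 to 67448504. In A549 it was a 35.9-kb peak at chromosome 16, 81554977 to 81590882, in the window with the largest loss. Its score of 334 was close to the median of all A549 peaks, 332.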

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

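Lists without chromosome 8 or without unplaced sequences, and every setting for strong peaks, for ratios of counts, for chromosomes and for windows, were chosen after the data were seen; the other alternatives were fixed before. No paired analysis was possible because each line has 1 pooled list, and no replicate could be left out for the same reason. Alternatives for promoters, distal peaks and gene lists were not run, for want of an hg19 annotation. The peak lists' unknown depth limits every comparison of number or length. Cover of chromosome 8 stayed at 0.683 to 0.718 of that in A549 under the 4 settings that change the lists. Under those settings all 80 values of the 20 named windows kept their direction and stayed within 1.5 times. This says little, since these windows were chosen for the largest differences, of at least 28.4 kb. Settings that drop low-scoring peaks or join near ones could hardly reverse those. All 24 checks of the 6 named peaks left them in a single list, but this outcome was fixed in advance. The settings only drop peaks or join those within 1000 bp, and the smallest gap to the other list was 1984 bp.

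The excess of MSR-A549-only over A549-only peaks, 1.21-fold with all peaks, turned to 0.968 with equal numbers of peaks and 0.886 with equal covered length. Both settings drop only weak MSR-A549 peaks, by construction. Equal numbers bring the ratio near 1 when the numbers of shared peaks are alike, and equal length left MSR-A549 with fewer peaks than A549. It was 1.24 at a score of at least 100, 1.29 with peaks merged, 1.16 when 50% of a peak had to be covered, 1.25 when peaks within 1000 bp counted as shared and 1.28 without chromosome 8. Under the settings in turn (score of 100, equal number, equal length, merged, 50% covered, within 1000 bp, without chromosome 8), the share of MSR-A549 peaks with an A549 counterpart was 75.2%, 74.1%, 75.0%, 74.1%, 67.5%, 76.3% and 71.1%. The share of A549 peaks was 78.6%, 73.2%, 72.5%, 78.4%, 70.0%, 79.6% and 75.6%. At a score of at least 100, 10138 peaks were found only in A549. For strong peaks, the excess at a score of at least 1000, 2.76-fold with all peaks, was 2.21 at the minimum of 100, 2.35 with equal length, 3.38 merged and 1.36 with 50% covered. The A549 counts were 365 at the minimum of 100 and 1137 with 50% covered, and the MSR-A549 count was 1543 with 50% covered. At 3100 they were 39 and 367 for A549 and 505 for MSR-A549. Where the settings do not explain these shifts by construction, the cause was not tested. Another 62 values of the main results stayed within their intervals or within 1.5 times.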

Other observations

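The tests of scores in the gained windows, of the chromosome 12 window and of leaving out further autosomes were chosen after the result was seen; for the other tests the outcome was not known, but the patterns themselves were.

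Joined domains of 100 kb or more that hold none of the named windows also differed between the lines. Cover was lower in MSR-A549 at chromosome 10, 33400001 to 33650000 (174.2 against 65.6 kb, 2.66-fold), and chromosome 12, 116800001 to 117050000 (133.4 against 54.9 kb, 2.43-fold). It was also lower at chromosome 8, 25050001 to 25200000 (101.9 against 26.2 kb, 3.88-fold). Cover was higher in MSR-A549 at chromosome 11, 122200001 to 122300000 (6.39 against 43.7 kb, 6.85-fold), and chromosome 3, 15300001 to 15400000 (8.58 against 48.2 kb, 5.62-fold). Chromosome 11 changed in both directions within 1 Mb, since cover at 122500001 to 122600000 was 49.3 kb in A549 and 9.41 kb in MSR-A549. These regions were chosen after their values were seen.

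On chromosome 8, lower cover in MSR-A549 was not the work of a few regions. Without the 20 windows that lost most, which held 23% of the net loss, the cover ratio was 0.738, still below the lowest of the other autosomes (0.879). Matched peaks were shorter along the chromosome, with a median log2 length ratio below the autosome-wide median in 27 of 30 segments (90.0%), against 213 of 524 elsewhere (40.6%). A change of the whole chromosome, such as a loss of DNA copies during selection, is a candidate explanation. Input reads, which would separate it from a change of chromatin along the chromosome, were not analysed here.

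The domains gained in MSR-A549 may be local changes of acetylation, since the 10 windows lie in 6 regions whose surroundings did not gain alike. In their flanks, 1 Mb wide on each side and starting 250 kb away, the median log2 cover ratio was 0.0089 (range -0.29 to 0.57). Windows of 1 region share much of their flanks, so this median counts some regions more than once. On chromosomes 4 and 6 and at chromosome 15, 59550001, flanks stood at -0.29 to -0.14. This argues against a gain of the surrounding chromosome segment there, though not against a narrower one. For the windows on chromosome 1 and from 67350001 to 67500000 on chromosome 15, flanks stood at 0.16 to 0.21, so a small segment gain is not excluded. A segment gain stays open for the chromosome 12 window, whose flanks stood at 0.57 while the window itself stood at 3.68. Whether peaks just above the calling threshold contribute was not decided by mean scores. The length-weighted mean score of MSR-A549 peaks was at least 500 in 10 of 10 windows, but also in 213 of the 213 windows with as much MSR-A549 cover, so the choice of windows fixes that outcome. The unweighted median reached 500 in only 6 of the 10. MSR-A549 peaks scoring under 100 covered at most 2.87 kb of a window, while all MSR-A549 peaks covered 37.8 to 49.0 kb. Peaks that weak thus made up little of the cover of these 10 windows. The resistant state and the continued presence of both drugs remain open as biological explanations, since no sample separates them.

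Chromosomes dense in peaks tended to have relatively less cover in MSR-A549, but weakly. Across the 22 autosomes, which are not independent replicates, Spearman's rho between peak density and cover ratio was -0.26 and Pearson's r -0.12; without the densest, chromosomes 17 and 19, they were -0.10 and -0.03, so the relation rests on those. A library difference that follows gene density or GC content could give such a trend, and within chromosomes rho was -0.17 (r -0.19, 544 segments), between the bounds set for and against it. Removing chromosomes 6 and 8 did not weaken the trend, with rho at -0.35 (r -0.29) and between -0.52 and -0.27 with any 1 further autosome left out, but without 6, 8, 17 and 19 it was -0.17 (r -0.14). The weak trend thus remained without 6 and 8. Whether they were its sole source was not decided, since -0.35 did not reach the -0.4 set beforehand for excluding it.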
